A study of Mus musculus with 16 samples.

How the data were processed

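Total RNA was measured by paired-end sequencing (NovaSeq, 100-base reads) in 16 mouse C57BL/6J placentas at E14.5. Per the labels, 4 placentas came from each combination of fetal sex (female, male) and sire diet (control, CON; high-fat, HF). The libraries are named by group and replicate number, as in HF_male replicate 3.

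The submitters' processing notes name Trim Galore 0.5.0, HISAT2 2.1.0, SAMtools 1.9, StringTie 2.1.2 and the mouse genome GRCm38 (mm10). Per the file headers, the deposited files came from StringTie 2.1.2, which estimated the transcripts of the Ensembl release 99 annotation and assembled no others. Each file lists 142647 transcripts of 55471 genes, and the deposited values of the authors are coverage, FPKM and TPM per transcript. The notes do not say whether the libraries kept the strand of the RNA, so overlapping genes and antisense partners were not separable. Reads of near-identical genes, such as the granzyme, prolactin, pregnancy-specific glycoprotein and alpha-globin copies and the repeated microRNAs within Sfmbt2, could be divided between copies in a way the files do not show. MicroRNA and transfer RNA genes are shorter than a read, so their TPM values are uncertain.

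Gene TPM was the sum of the TPM of all transcripts with the same gene identifier. Gene types were taken from GENCODE M21 by identifier, which covered 55230 of the 55471 genes and 14736 of the 14744 tested genes; 54937 had the same start and end in both annotations. Genes with a TPM of at least 1 in at least 4 of the 16 libraries were tested. Values were analysed as log2(TPM + 1), so a log2 difference understates the change of genes with low TPM.

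The depth was taken as the coverage of each transcript times its length, summed. It ranged from 3.49 gigabases in HF_female replicate 3 to 7.07 gigabases in CON_male replicate 2; divided by the read length of 100 bases, the same product gave the read equivalents of a gene. Between 13362 and 14924 genes per library reached a TPM of 1. The files give no read counts, so no counting interval is given for any value.

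A linear model with the 4 groups was fitted to each gene with limma 3.58.1 (R 4.3.3), with an intensity trend in the prior variance and 12 residual degrees of freedom. The comparisons were HF minus CON in libraries labelled female, the same in libraries labelled male, the average of both, the difference between both (interaction), and male minus female averaged over the diets. P-values were adjusted by the Benjamini-Hochberg method over all genes within each comparison, with a threshold of 0.05; tests are two-sided. No label names a litter, dam, sire or batch, so the p-values measure the spread between these samples, and whether placentas shared a litter is not known. Errors of log2 differences are standard errors (SE) of the model; errors of TPM values are standard deviations (SD) over 4 placentas unless another n is given.

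In total 43 gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the first set of other settings. Of the lists, 40 had at least 3 tested members and were tested for diet, and 2 lists of sex-linked genes were added for the sex comparison; a list of lymphocyte markers had too few tested members. Lists were tested with camera of limma, which compares the members of a list with all other genes, with a preset correlation between genes of 0.01. Adjustment was over the lists within a comparison. Beside it stands the adjusted p with a correlation estimated for each list, whose median over the lists was 0.641 in the diet comparisons. The rotation test fry of limma, which asks whether the members of a list move one way, gave 0 lists in each comparison, and its mixed form, which asks for changes in either direction, also gave 0. Members of the lists were adjusted over the list alone as well.

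For each diet comparison the genes to be named were those passing the threshold with a mean TPM of at least 2 in the higher group and no overlap between groups, or the same sign in both sexes for the average, up to 10 upward and 10 downward. For the interaction and sex comparisons they were the 10 of smallest p. Since fewer than 10 passed, the names were filled to 10 by the smallest unadjusted p, and these are given as not passing. Clone and gene model names and pseudogenes were left out of the ranking. From each list up to 4 members of smallest unadjusted p could be named.

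Comparisons of single values between groups used exact permutation tests. The other settings fixed at that point were a pseudocount of 0.25, filters at a TPM of 5 and without a minimum, FPKM in place of TPM, median ratio scaling, quantile normalization, limma without the trend or with a robust prior, voom on the read equivalents, sample weights, a fit to 1 sex alone, the replicate number as a block, the decidua or junctional zone list mean as a covariate, an estimated correlation, fry, and leaving out each library. After the data were seen, 6 more were added, which left out libraries whose sex-linked RNA went against their label or which held the most yolk sac RNA, rescaled TPM over protein-coding genes, used the yolk sac list mean as a covariate, joined median ratio scaling with the yolk sac and decidua covariates, or left sex out of the model. The lists called in the interaction and sex comparisons were then recomputed under the same settings as the diet lists, and the natural killer cell list also with the decidua covariate.

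The procedure was tested on simulated data with 200 changed genes of 14744 in each of 10 draws. With independent genes, the female comparison recovered 8.66% of genes changed by a log2 difference of 0.5, 84.3% at 1 and 98.8% at 2; the male comparison recovered 11.3%, 83.7% and 98.6%, and the average 46.6%, 96.9% and 99.1%. Over the 10 draws together, at most 0.0468% of unchanged genes were called in any diet comparison with independent genes. When whole libraries were reassigned, the highest share over the 10 draws together was 6.26%, in the male comparison, and single draws could lie above it. Camera with the preset correlation called 0 lists of independent genes. When whole libraries were reassigned at random, so that genes kept their correlations, it called a median of 13 of 40 lists in the female, 14 in the male and 13 in the averaged comparison, with up to 22. With the estimated correlation the median was 0 and the highest 3. Calls of lists at the preset correlation are therefore given with the estimated one.

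Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. The series also describes sperm chromatin profiles of histone H3K4me3, which are not analysed here. Differences between transcripts of a gene were not tested.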

Results

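Total RNA of 16 mouse placentas at E14.5 was sequenced, 4 placentas for each fetal sex and sire diet. From 6 weeks of age the sires ate either control food or food high in fat, over 8 to 10 weeks. The comparisons address whether a father's diet goes with a different placental transcriptome in daughters and in sons. The depth was 3.49 to 7.07 gigabases of sequence on annotated transcripts per library, and 14744 genes were tested.

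The placentas expressed the hormone and trophoblast genes of the mouse placenta at high levels. Prl3b1, a placental lactogen, made up 3.12% ± 0.45 (SD, n = 16) of the protein-coding TPM, and Tpbpa, a marker of spongiotrophoblast, made up 2.86% ± 0.4. The prolactin family as a whole held 8.9% ± 1.05, the globins 3.55% ± 0.75 and the mitochondrially encoded genes 1.27% ± 0.147. The protein-coding total includes the gene model Gm10800, at 1.14% ± 4.11, which held 86600 TPM in CON_female replicate 4 and lowers the other shares there. A pair of RNAs outside the protein-coding genes, Rn7s1 and Rn7s2, both copies of the 7SL RNA of the signal recognition particle, held 34.8% ± 5.55 of all TPM, from 20.4% in CON_female replicate 3 to 41.7% in CON_male replicate 1.

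Sex-linked RNA followed the sex label in 13 of the 16 libraries and went against it in 3, all of them controls. The X-inactivation RNA Xist stood at 18.5 TPM in CON_male replicate 1 and 25.8 TPM in CON_male replicate 4. The sum of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was 0.00114 TPM in the first and 0 in the second. CON_female replicate 1 held 5.8 TPM of Xist and 26.2 TPM of the Y-linked sum. In the libraries without Y-linked RNA the sum was at most 0.0875 TPM and Xist lay between 10.3 and 25.8 TPM. In the 7 libraries with Y-linked RNA, Xist lay between 1.4 and 5.8 TPM. All groups below follow the labels, so that the control group of each sex holds libraries of the other kind, and the counts of genes and of diet lists without these 3 libraries are given beside the comparisons.

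**Figure D1:**
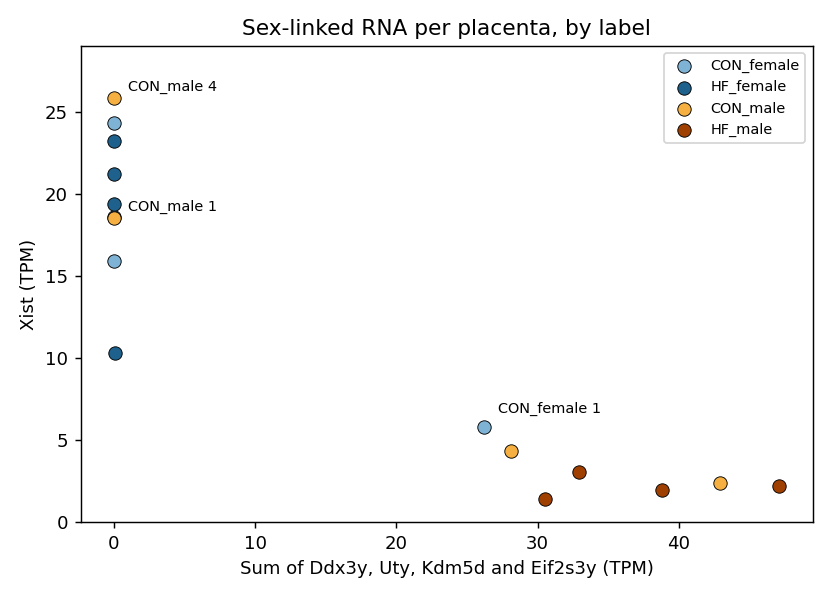
Each point is 1 placenta, with the summed TPM of Ddx3y, Uty, Kdm5d and Eif2s3y on the x axis and the TPM of Xist on the y axis, coloured by labelled group. The 3 named control libraries lie with the other sex: CON_male replicates 1 and 4 have a Y-linked sum of at most 0.00114 TPM, and CON_female replicate 1 has 26.2 TPM.

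In the libraries labelled female, no gene passed the test for the sire's diet. Of the 10 genes of smallest p, mt-Tf (ENSMUSG00000064336, chromosome MT, 1 to 68), the mitochondrial transfer RNA for phenylalanine, had 3.09 ± 0.758 TPM with control and 1.30 ± 0.573 TPM with high-fat sires, a log2 difference of -0.85 ± 0.186 (SE, n = 4 per group). Fdx2 (ENSMUSG00000079677, chromosome 9, 21067520 to 21073614), a mitochondrial ferredoxin of iron-sulphur cluster assembly, had 5.65 ± 2.56 and 2.38 ± 0.547 TPM. Cyp2ab1 (ENSMUSG00000022818, chromosome 16, 20308387 to 20325404), a cytochrome P450 gene, had 4.07 ± 2.65 and 1.26 ± 0.429 TPM, and Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), which encodes lactoferrin, had 8.31 ± 7.32 and 1.89 ± 1.14 TPM. For these 4 genes every high-fat placenta lay below every control. The gap for Fdx2 was 3.126 TPM in HF_female replicate 1 against 3.129 TPM in CON_female replicate 2. Ctnnbl1 (chromosome 2, 157737401 to 157891614) went the other way without overlap, from 26.4 ± 4.64 to 36.0 ± 4.84 TPM. All were picked by smallest p, so a lack of overlap, here and in the comparisons below, is no separate support. The others were Fa2h, a fatty acid hydroxylase (log2 difference 0.62), the theta globin Hbq1b (0.63), the iron hormone hepcidin Hamp (0.77), Chic2 (0.68) and the DNA exonuclease Trex1 (-0.66). The reads of Fdx2 and of an overlapping gene model could not be separated, and mt-Tf is shorter than a read. The limma test passed 0 of 14744 genes (smallest adjusted p = 0.9999), and voom passed 0. At an unadjusted p under 0.05 limma had 104 genes, where 737 would come up by chance, and voom had 253. The limma number was 396 after median ratio scaling. Leaving out single libraries gave 95 (CON_female replicate 1) to 697 (CON_female replicate 3). So few small p-values are therefore no evidence against a difference. Without the 3 libraries against their sex label 0 genes passed again. Among members of the lists, 1 gene passed when adjusted over the list alone, Ltf among the neutrophil markers (adjusted p = 0.0389).

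Of the 40 gene lists, 8 were called in the libraries labelled female at the preset correlation, 3 above and 5 below all other genes, and 0 with the estimated correlation (smallest adjusted p = 0.834); 6 were called without the 3 libraries against their sex label. The 13 mitochondrially encoded genes all lay below 0, with a mean log2 difference of -0.25 (adjusted p = 3.02e-13; adjusted p = 0.834 with an estimated correlation). Among them mt-Nd2, a subunit of respiratory complex I, had 82.7 ± 18.6 TPM with control and 62.4 ± 9.33 TPM with high-fat sires. That mean was -0.14 without CON_female replicate 4 and also -0.14 without HF_female replicate 3. Of 20 fixed uterine natural killer cell genes only 8 were tested, mostly granzymes, whose near-identical copies could share reads. All 8 lay below 0, with a mean of -0.43 (camera, adjusted p = 2.15e-07, and adjusted p = 0.834 with an estimated correlation). With an estimated correlation of 0.82, these genes are not separate observations. Gzmf had 206 ± 77.5 and 151 ± 82.6 TPM. The mean of this list was -0.20 without HF_female replicate 3, -0.24 without CON_female replicate 3 and -0.73 without HF_female replicate 4.

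The other called lists held smaller differences, each with an adjusted p = 0.998 with an estimated correlation. Markers of the decidua, the maternal layer, had 18 of 24 members below 0 and a mean of -0.10 (adjusted p = 0.0012), with Cd55 at 31.1 and 22.3 TPM. The mean was -0.25 without CON_female replicate 2, -0.16 without CON_female replicate 4, -0.22 without HF_female replicate 4 and 0.11 without CON_female replicate 3, and the call ended without HF_female replicate 2 (0.026, adjusted p = 0.67). Pregnancy-specific glycoprotein genes, secreted by trophoblast, had 12 of 13 members above 0 and a mean of 0.16 (adjusted p = 0.000337), with Psg26 at 436 and 562 TPM. The call ended without HF_female replicate 1 (0.055, adjusted p = 0.969) and without CON_female replicate 4 (0.071, adjusted p = 0.0722), while the mean was 0.28 without CON_female replicate 3 and 0.10 without CON_female replicate 1. All 16 erythroid genes lay above 0, with a mean of 0.13 (adjusted p = 0.0106), and the alpha globin Hba-a2 stood at 3747 and 4265 TPM. This call ended without CON_female replicate 1 (0.045, adjusted p = 0.25) and without HF_female replicate 3 (0.077, adjusted p = 0.997). The mean was 0.31 without CON_female replicate 3, 0.085 without CON_female replicate 4, 0.20 without HF_female replicate 1 and 0.088 without HF_female replicate 2.

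Interferon response genes had 20 of 26 members below 0 and a mean of -0.084 (adjusted p = 0.0017; adjusted p = 0.998 with an estimated correlation) in libraries labelled female, with Ifit1 at 6.32 and 4.83 TPM. The call ended without HF_female replicate 1 (0.012, adjusted p = 0.414) and CON_female replicate 2 (-0.068, adjusted p = 0.754). The mean was 0.009 without CON_female replicate 3, -0.006 without HF_female replicate 3, -0.19 without HF_female replicate 2, -0.13 without CON_female replicate 1, -0.15 without CON_female replicate 4 and -0.16 without HF_female replicate 4. Inflammation genes had 9 of 15 members below 0 and a mean of -0.097 (adjusted p = 0.0365; adjusted p = 0.998 with an estimated correlation), with the chemokine gene Ccl2 at a log2 difference of -0.49. That call ended without CON_female replicate 1 (adjusted p = 0.107), CON_female replicate 2 (adjusted p = 0.39) or HF_female replicate 2 (adjusted p = 0.396). With CON_female replicate 3 left out the mean was 0.038. The mean was -0.041 without HF_female replicate 3, -0.18 without HF_female replicate 4 and also -0.18 without CON_female replicate 4. Glucose and amino acid transporters had 15 of 19 members above 0 and a mean of 0.091 (adjusted p = 0.0328; adjusted p = 0.998 with an estimated correlation), with the glucose transporter Slc2a3 at a log2 difference of 0.42. The transporter call ended without CON_female replicate 2 (0.005, adjusted p = 0.262), CON_female replicate 1 (0.045, adjusted p = 0.135), CON_female replicate 3 (0.22, adjusted p = 0.0658), HF_female replicate 2 (0.049, adjusted p = 0.0532) or HF_female replicate 3 (0.14, adjusted p = 0.0964), and the mean was 0.044 without HF_female replicate 4.

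In the libraries labelled male, no gene passed the test for the sire's diet either. Tnc (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), the matrix glycoprotein tenascin C, had 1.29 ± 0.443 TPM with control and 4.53 ± 3.04 TPM with high-fat sires, a log2 difference of 1.15 ± 0.292 (SE, n = 4 per group). Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), an interferon-induced membrane protein gene, had 1.32 ± 0.405 and 3.08 ± 1.17 TPM. The pancreatic polypeptide gene Ppy (log2 difference 0.53) and the microRNA genes Mir382 (0.83), Mir669d (0.62) and Mir297c (0.75) also lay above all controls in every high-fat placenta, and the noncoding Lncppara lay below all of them, at 0.345 against 1.22 TPM. Pitpna, a phosphatidylinositol transfer protein gene, had 23.0 ± 3.72 and 40.2 ± 9.70 TPM with overlap, and the germ cell transcription factor gene Sohlh2 had 0.670 and 2.93 TPM. Xist had 12.8 ± 11.3 and 2.15 ± 0.688 TPM, with 18.5 and 25.8 TPM in the 2 control libraries labelled male that lack Y-linked RNA. The limma test passed 0 of 14744 genes (smallest adjusted p = 0.998), with 231 at an unadjusted p under 0.05, and voom passed 0, with 551 unadjusted. Without the 3 libraries against their sex label the count was again 0, and 0 members of the lists passed when adjusted over the list alone.

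Yolk sac endoderm genes stood out among the lists in the libraries labelled male: 24 of 25 members lay above 0, with a median log2 difference of 2.28 and a mean of 1.98 (adjusted p = 1.04e-16; adjusted p = 0.568 with an estimated correlation). Afp, which encodes alpha-fetoprotein, had 220 ± 372 TPM with control and 3242 ± 5809 TPM with high-fat sires, and Ttr, which encodes transthyretin, had a log2 difference of 3.11 ± 1.37. HF_male replicate 3 alone held 12000 TPM of Afp, and without it the mean of the list was 0.98, called at the preset correlation (adjusted p = 0.998 with an estimated correlation). The mean was 2.71 (adjusted p = 0.152 with an estimated correlation) without the 3 libraries against their sex label. Those include CON_male replicate 4, whose mean log2 value of this list was 4.63, against 1.80 to 2.46 in the other CON_male placentas. Uterine natural killer cell genes lay below 0 in 7 of 8 members, with a mean of -0.50 (adjusted p = 1.47e-10; adjusted p = 0.38 with an estimated correlation), and Gzmd had 147 and 92.3 TPM. Decidua genes lay below 0 in 22 of 24 members, with a mean of -0.29 (adjusted p = 1.17e-19; adjusted p = 0.38 with an estimated correlation); the estrogen receptor gene Esr1 had 8.32 ± 3.26 and 4.55 ± 1.46 TPM and the progesterone receptor gene Pgr 7.51 and 4.67 TPM. The natural killer cell mean was -0.25 without CON_male replicate 1 and -0.27 without HF_male replicate 4, and the decidua mean was -0.19 without CON_male replicate 4. After median ratio scaling with the yolk sac and decidua list means as covariates the natural killer cell call ended (mean -0.12, adjusted p = 0.866), and with the decidua covariate alone the mean was -0.27 (adjusted p = 1.17e-08; adjusted p = 0.54 with an estimated correlation). Without the 3 libraries against their sex label that call also ended (mean -0.10, adjusted p = 0.197) and the decidua mean was -0.11 (adjusted p = 0.00337; adjusted p = 0.854 with an estimated correlation).

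**Figure D2:**
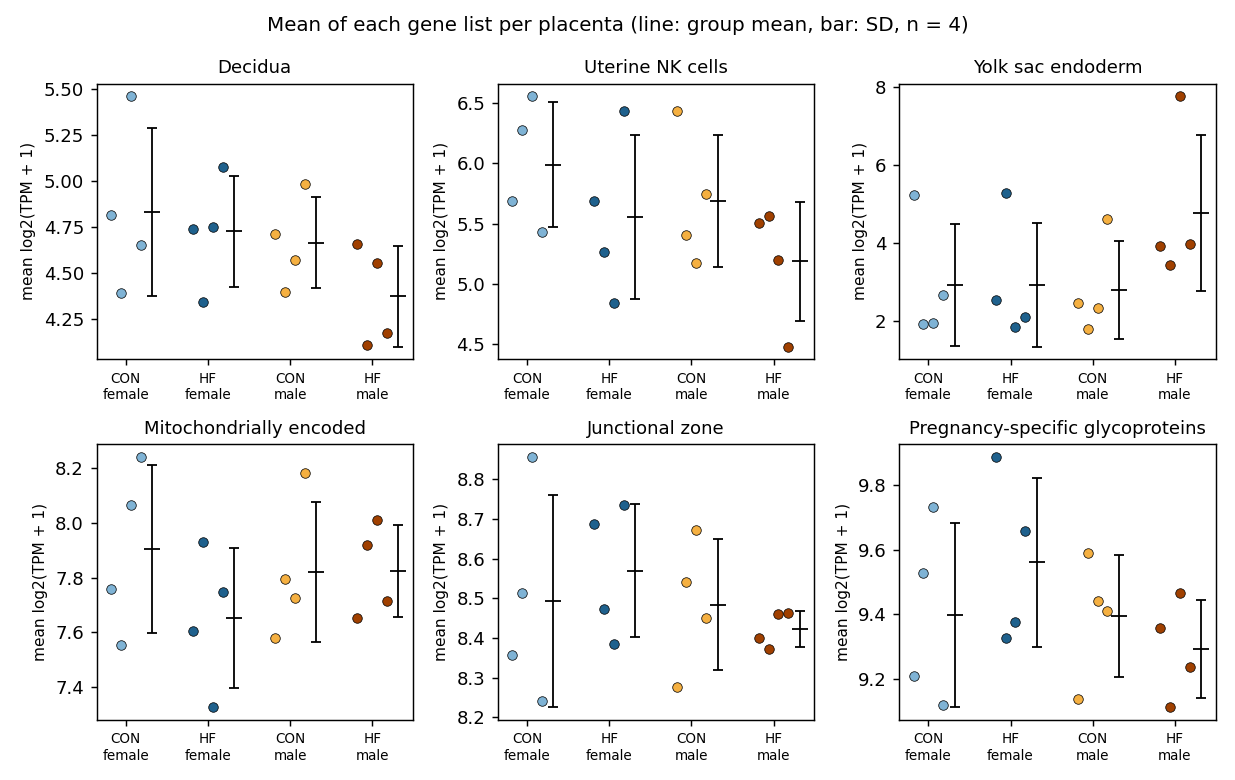
Each point is the mean log2(TPM + 1) of a gene list in 1 placenta, by labelled group; the line is the group mean and the bar the SD (n = 4). HF_male replicate 3 stands alone in the yolk sac endoderm list at 7.78, while the other HF_male placentas lie between 3.45 and 3.97.

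Of the trophoblast lists, 3 were called slightly below the other genes in the libraries labelled male, each with an adjusted p = 0.999 with an estimated correlation. Giant cell genes (mean 0.044, adjusted p = 0.403), syncytiotrophoblast genes (0.046, adjusted p = 0.243) and labyrinth progenitor genes (0.090, adjusted p = 0.977) were not called. The median over all tested genes was itself 0.084 in these libraries. Junctional zone genes had 24 of 35 members below 0 and a mean of -0.061 (adjusted p = 2.25e-06), which was 0.002 without CON_male replicate 3 and -0.13 without CON_male replicate 1. The prolactin family had 17 of 25 below 0 and a mean of -0.063 (adjusted p = 7.04e-05), with Prl3c1 at 49.1 and 39.7 TPM. That mean was 0.017 without CON_male replicate 3, -0.13 without CON_male replicate 1 and -0.035 without HF_male replicate 2, and the call ended without HF_male replicate 3 (-0.053, adjusted p = 0.178). Pregnancy-specific glycoprotein genes had 10 of 13 below 0 and a mean of -0.10 (adjusted p = 3.79e-05), with Psg16 at 3114 and 2586 TPM. The call ended without CON_male replicate 2 (-0.037, adjusted p = 0.161), and the mean was -0.19 without CON_male replicate 1, -0.042 without HF_male replicate 2 and -0.16 without HF_male replicate 3.

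The remaining called lists of the libraries labelled male each had an adjusted p = 0.999 with an estimated correlation. Cholesterol synthesis genes had 23 of 24 members above 0 and a mean of 0.22 (adjusted p = 0.0129), with the lanosterol synthase gene Lss at 5.72 and 8.79 TPM. Without HF_male replicate 3, which holds the most yolk sac RNA, the mean was -0.025 (adjusted p = 0.307); the call also ended without CON_male replicate 2 (0.16, adjusted p = 0.0641) or CON_male replicate 3 (0.29, adjusted p = 0.154). Endoplasmic reticulum stress genes had 17 of 22 below 0 and a mean of -0.051 (adjusted p = 0.00015), with the chaperone gene Dnajb9 at 27.4 and 23.1 TPM. This call ended without HF_male replicate 2 (0.003, adjusted p = 0.0642), and the mean was 0.024 without CON_male replicate 3, -0.12 without CON_male replicate 1 and -0.11 without HF_male replicate 3. Replication histone genes had 38 of 57 below 0 and a mean of -0.066 (adjusted p = 1.22e-06). That call ended without CON_male replicate 1 (-0.028, adjusted p = 0.0809); the mean was 0.077 without CON_male replicate 3, 0.057 without HF_male replicate 1, -0.042 without HF_male replicate 4, -0.10 without HF_male replicate 2 and between -0.18 and -0.15 without CON_male replicate 2, CON_male replicate 4 or HF_male replicate 3. Fetal endothelium genes were called below other genes (camera, adjusted p = 0.0424) although their median and mean were both 0.004. The median over all tested genes was 0.084 in this comparison. The mean of this list was -0.075 after median ratio scaling, and the call ended when any 1 of CON_male replicates 3 and 4, HF_male replicates 1, 3 and 4 and HF_female replicates 2 and 3 was left out (adjusted p = 0.0504 to 0.48). Its means ran from -0.081 without CON_male replicate 1 to 0.085 without CON_male replicate 3. In total 10 of 40 lists were called in the libraries labelled male, 2 above and 8 below, and 0 with the estimated correlation. There were 3 above and 8 below after median ratio scaling, and 5 above and 5 below after quantile normalization. Without the 3 libraries against their sex label 17 were called, 8 above and 9 below, and 0 with the estimated correlation.

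Averaged over both sexes, natural killer cell and decidua genes lay lower and yolk sac genes higher with high-fat sires. All 8 natural killer cell genes lay below 0, with a mean log2 difference of -0.47 (adjusted p = 5.21e-15; adjusted p = 0.269 with an estimated correlation), and Gzme had a log2 difference of -0.53 ± 0.24 (SE, n = 8 per diet). Decidua genes lay below 0 in 22 of 24 members, with a mean of -0.20 (adjusted p = 4.52e-18; adjusted p = 0.395 with an estimated correlation), and the tryptophan dioxygenase gene Tdo2 had -0.35. The decidua mean was -0.091 without CON_female replicate 3, and without the 3 libraries against their sex label it was -0.11 and the natural killer cell mean -0.32, both still called at the preset correlation (adjusted p = 0.0002 and 4.44e-06) and not otherwise (adjusted p = 0.909 for each with an estimated correlation). With the decidua list mean as a covariate the natural killer cell mean was -0.31 (adjusted p = 6.8e-13; adjusted p = 0.171 with an estimated correlation), and after median ratio scaling with the yolk sac and decidua covariates it was -0.23 and no longer called (adjusted p = 0.131). Yolk sac endoderm genes lay above 0 in 24 of 25 members, with a median of 1.11 and a mean of 0.99 (adjusted p = 1.02e-08; adjusted p = 0.974 with an estimated correlation). Their call ended without CON_female replicate 3 (0.82, adjusted p = 0.572), and the mean was 0.49 without HF_male replicate 3 and 0.60 without HF_female replicate 2. It was 1.74 (adjusted p = 4.11e-52; adjusted p = 0.131 with an estimated correlation) without the 3 libraries against their sex label. Those 3 include CON_female replicate 1 and CON_male replicate 4, the controls with the highest mean log2 values of this list (5.23 and 4.63). In libraries labelled female alone the mean difference of this list was 0.003 (adjusted p = 0.854). That mean was 0.77 without CON_female replicate 1 (adjusted p = 6.2e-09), -0.78 without HF_female replicate 2 (adjusted p = 5.64e-05), -0.33 without CON_female replicate 3 (adjusted p = 4.77e-08) and 0.28 without HF_female replicate 4 (adjusted p = 0.0139). With an estimated correlation these were not called (adjusted p = 0.996, 0.993, 0.997 and 0.997). The 13 mitochondrially encoded genes all lay below 0, with a mean of -0.13 (adjusted p = 1.02e-08; adjusted p = 0.968 with an estimated correlation), which was -0.065 without CON_male replicate 4, -0.069 without CON_female replicate 4 and -0.070 without HF_female replicate 3. In libraries labelled male alone the mean of that list was 0.004, and -0.091 after median ratio scaling.

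**Figure D3:**
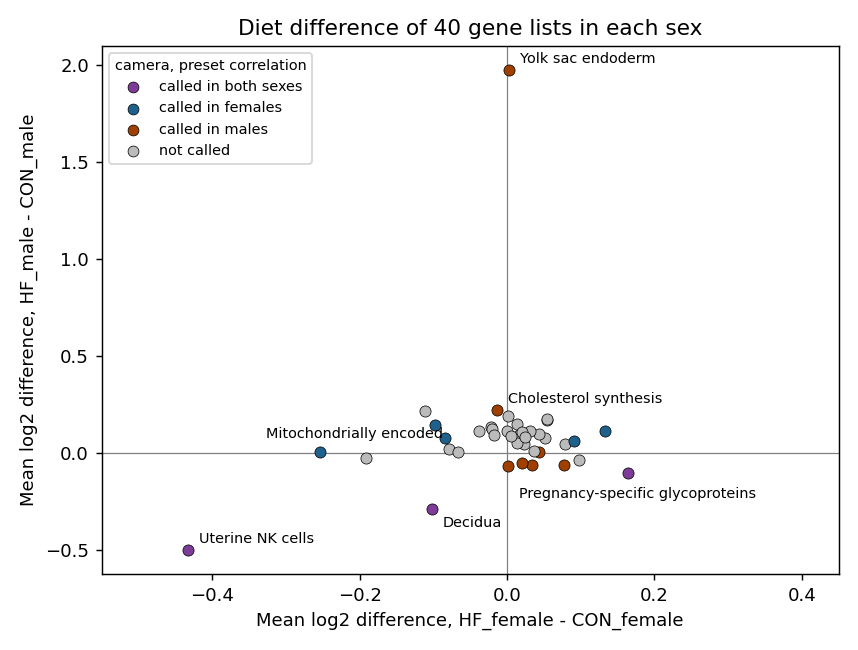
Each point is 1 of 40 gene lists, with the mean log2 difference between high-fat and control sires in libraries labelled female on the x axis and in libraries labelled male on the y axis; colours show camera calls at the preset correlation. Uterine natural killer cell genes lie at -0.43 and -0.50 and decidua genes at -0.10 and -0.29, while yolk sac endoderm genes lie at 0.003 (0.77 without CON_female replicate 1, -0.78 without HF_female replicate 2) and 1.98 (0.98 without HF_male replicate 3); of the lists called in males, the mean of fetal endothelium changes sign with the scaling.

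The other 4 lists called in the average had means near 0. Replication histone genes had 36 of 57 members below 0 and a mean of -0.032 (adjusted p = 2.53e-05), endoplasmic reticulum stress genes 14 of 22 below 0 and -0.015 (adjusted p = 0.0153), and the prolactin family 14 of 25 below 0 and -0.014 (adjusted p = 0.0192). Heat shock genes had 7 of 15 below 0, a median of 0.003 and a mean of -0.033 (adjusted p = 0.0153), with the small heat shock gene Hspb8 at -0.24. Each had an adjusted p = 0.974 with an estimated correlation. Leaving out single libraries moved each of these means across 0. Histones ran from -0.12 without HF_female replicate 2 to 0.064 without CON_female replicate 3. The stress genes ran from -0.066 without CON_female replicate 4 to 0.071 without CON_female replicate 3, the prolactin family from -0.064 to 0.041 without the same libraries, and heat shock genes from -0.081 without CON_female replicate 2 to 0.055 without CON_female replicate 3. The histone call ended without CON_male replicate 1 (adjusted p = 0.0577). The stress call ended without CON_female replicates 2 and 3, CON_male replicate 2, HF_female replicate 2 or HF_male replicate 2 (adjusted p = 0.0978 to 0.561). The prolactin call ended without CON_female replicates 1 and 2, CON_male replicate 2, HF_female replicate 2 or HF_male replicates 2 and 3 (adjusted p = 0.0732 to 0.65). The heat shock call ended without CON_female replicates 1 and 3, CON_male replicate 3, HF_female replicate 1 or HF_male replicates 1 and 2 (adjusted p = 0.0515 to 0.123). In total 8 of 40 lists were called in the average, 1 above and 7 below, and 0 with the estimated correlation. There were 1 above and 6 below after median ratio scaling, and 3 above and 6 below after quantile normalization. Without the 3 libraries against their sex label 17 were called, 6 above and 11 below, and 0 with the estimated correlation.

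Of single genes in the average, Cyp2ab1 had a log2 difference of -0.70 ± 0.199 (SE, n = 8 per diet), and the mitochondrial transfer RNAs mt-Tt and mt-Td had -0.41 ± 0.125 and -0.50 ± 0.156. C1qb, a complement gene of macrophages, had 3.63 and 2.94 TPM in control libraries labelled female and male and 4.32 and 4.63 TPM in the high-fat ones. Ppih, a cyclophilin of the spliceosome, had -0.35 ± 0.109. The microRNA genes Mir453 (0.57), Mir382 (0.55), Mir466c-1 (0.46) and Mir669d (0.42) lay above 0, and the ribosomal RNA copy n-R5s118 (-0.52) below. The limma test passed 0 genes (smallest adjusted p = 0.9991), with 182 at an unadjusted p under 0.05, and voom passed 0, with 505 unadjusted; 0 members passed when adjusted over the list alone. Without the 3 libraries against their sex label the count was again 0.

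The other 32 lists were not called in the average. Imprinted genes had 42 of 49 members above 0 (adjusted p = 0.0645), such as the noncoding RNA gene Meg3 (log2 difference 0.52 ± 0.23) and Nnat (0.68). Of blood and immune lists, erythroid genes had 15 of 16 members above 0 (adjusted p = 0.0801), primitive globins 3 of 3 (adjusted p = 0.704), platelets and megakaryocytes 6 of 7 (adjusted p = 0.695), macrophages 12 of 15 (adjusted p = 0.209), neutrophils 4 of 7 (adjusted p = 0.321), interferon response 13 of 26 (adjusted p = 0.0554) and inflammation 10 of 15 (adjusted p = 0.277). The median of the neutrophil list was 0.053 and its mean -0.11. Of trophoblast and vascular lists, junctional zone genes had 20 of 35 members above 0 (adjusted p = 0.103), pregnancy-specific glycoproteins 10 of 13 (adjusted p = 0.695), giant cells 10 of 17 (adjusted p = 0.667), syncytiotrophoblast 14 of 19 (adjusted p = 0.894), labyrinth progenitors 9 of 11 (adjusted p = 0.88), glycogen storage 11 of 15 (adjusted p = 0.851), fetal endothelium 15 of 24 (adjusted p = 0.367), angiogenic factors 15 of 21 (adjusted p = 0.547), stroma and pericytes 14 of 21 and collagens of the matrix 17 of 22 (adjusted p = 0.704 and 0.894).

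Among metabolic lists in the average, glucose and amino acid transporters had 15 of 19 members above 0 (adjusted p = 0.457), with Slc2a3 at a log2 difference of 0.32. Lipid transport and oxidation had 25 of 32 members above 0 (adjusted p = 0.695), cholesterol synthesis 23 of 24 (adjusted p = 0.313) and nuclear genes of oxidative phosphorylation 76 of 93 (adjusted p = 0.683). Steroid synthesis had 10 of 15 (adjusted p = 0.255), with a median of 0.048 and a mean of -0.030; the glucocorticoid-activating enzyme gene Hsd11b1 had -0.37. Insulin-like growth factor signalling had 21 of 25 (adjusted p = 0.704), with Igf2 at 0.18. Of stress and growth lists, hypoxia response had 21 of 29 members above 0 (adjusted p = 0.704), oxidative stress 17 of 20 (adjusted p = 0.667), immediate early genes 12 of 16 (adjusted p = 0.667), cell cycle 29 of 34 (adjusted p = 0.518), ribosomal proteins 77 of 85 (adjusted p = 0.313), mitochondrial ribosomal proteins 65 of 82 (adjusted p = 0.704) and proteasome 34 of 38 (adjusted p = 0.894). DNA methylation and chromatin genes had 25 of 29 (adjusted p = 0.316), with the DNA methyltransferase gene Dnmt3a at 0.27. The median over all tested genes was itself 0.054, and the sign of the mean differed between scalings in 16 of the 40 lists, none of whose means as deposited exceeded 0.055 in size.

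The interaction asks whether the difference with the sire's diet itself differed between the sexes. Trpv6, a calcium channel gene of placental transport, had 2.16 and 1.23 TPM with control and high-fat sires in libraries labelled female and 1.20 and 3.20 TPM in those labelled male, a difference between the log2 differences of 1.37 ± 0.393 (SE, n = 4 per group). Igfbp5, an insulin-like growth factor binding protein gene, had 2.07 and 1.31 TPM in the first and 1.79 and 2.68 TPM in the second (0.84 ± 0.244). The other genes of smallest p were mt-Tf (1.03), Sohlh2 (1.54), Fdx2 (1.02), Snord23 (0.94), the cardiac troponin gene Tnnt2 (0.71), Ifitm1 (0.92), Ltbp1 (0.83), a binding protein gene of latent transforming growth factor beta, and Sfxn4 (0.74). The limma test passed 0 genes (smallest adjusted p = 1), with 112 at an unadjusted p under 0.05, and voom passed 0, with 254 unadjusted; 0 members passed when adjusted over the list alone. Without the 3 libraries against their sex label 1 gene passed, the gene model Gm49909, named after its values were seen. Across the 14744 genes, which are not independent replicates, the log2 differences of the sexes had a Pearson r of 0.021, and 60.8% of genes had the same sign in both.

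Of the 40 lists, 15 were called for the interaction at the preset correlation, 5 above and 10 below, and 0 with the estimated correlation (smallest adjusted p = 0.972). All 13 pregnancy-specific glycoprotein genes lay below 0, with a mean of -0.27 (adjusted p = 7.70e-10), and all 13 mitochondrially encoded genes lay above it, with a mean of 0.26 (adjusted p = 0.000542). Yolk sac endoderm genes had a mean of 1.97 (adjusted p = 2.28e-12), and stroma and pericyte genes 0.33 (adjusted p = 0.0286), with the collagen gene Col6a1 at 1.99, 1.66, 1.69 and 5.46 TPM in CON_female, HF_female, CON_male and HF_male. Junctional zone genes had a mean of -0.14 (adjusted p = 6.03e-08) and decidua genes -0.19 (adjusted p = 2.79e-06). Each of these had an adjusted p = 0.972 with an estimated correlation. The yolk sac mean was 1.21 without CON_female replicate 1 and 0.97 without HF_male replicate 3. The decidua mean was -0.001 and no longer called without the 3 libraries against their sex label (adjusted p = 0.622), while every single library left out kept the call. It was -0.40 without CON_female replicate 3, -0.32 without HF_female replicate 2 and -0.28 without HF_male replicate 1. It was -0.042 without CON_female replicate 2, -0.071 without HF_female replicate 4, -0.083 without CON_male replicate 4, -0.10 without HF_male replicate 2 and -0.12 without HF_male replicate 4. The mitochondrial call ended without CON_female replicate 4 (0.14, adjusted p = 0.3) or CON_male replicate 3 (0.23, adjusted p = 0.223), and the mean was 0.15 without HF_female replicate 3. The stroma call ended when any 1 of CON_female replicate 4, CON_male replicates 2 and 3, HF_female replicate 3 and HF_male replicates 1, 2 and 3 was left out (adjusted p = 0.0571 to 0.385). The stroma mean was 0.14 without HF_male replicate 3, 0.17 without CON_female replicate 3 and 0.20 without HF_female replicate 3. The glycoprotein mean was -0.17 without CON_female replicate 4 and -0.16 without HF_female replicate 1, and this list and the junctional zone list kept their calls with each single library left out. The junctional zone mean was -0.26 without CON_female replicate 3, -0.21 without CON_male replicate 1, -0.083 without HF_female replicate 4, -0.075 without CON_male replicate 3 and -0.054 without CON_female replicate 4. After median ratio scaling with the yolk sac and decidua covariates the calls of the glycoprotein, junctional zone, mitochondrial and stroma lists all ended (adjusted p = 0.117, 0.304, 0.335 and 0.299). When the labels were permuted within each sex, 0 of the 40 list means differed between the sexes (exact permutation test, 4900 assignments, smallest adjusted p = 0.926).

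The comparison of libraries labelled male and female gives the size of a known difference, made smaller by the 3 libraries against their label. All 4 Y-linked genes were higher in libraries labelled male, with a mean log2 difference of 2.02 (adjusted p = 6.37e-23; adjusted p = 0.00883 with an estimated correlation). That mean was 3.14 without the 3 libraries. Xist was lower, by -1.63 ± 0.352 (SE, n = 8 per sex). Eif2s3y had 2.36 ± 0.499, Ddx3y 2.54 ± 0.588, Uty 1.74 ± 0.409 and Kdm5d 1.43 ± 0.327. These 5 genes passed when adjusted over the list alone (adjusted p = 0.000405 for each Y-linked gene and 0.00156 for Xist) but not over all genes, where the smallest adjusted p among them was 0.497. Over all genes 2 passed. Fdx2 was higher in libraries labelled male (0.94 ± 0.154, adjusted p = 0.0463; 7.84 ± 1.21 against 4.01 ± 2.45 TPM), and the pseudogene Gm8493 (chromosome 5, 109551892 to 109554156), named after its values were seen, was lower (-1.01, adjusted p = 0.0463). Fdx2 overlaps the gene model Gm38431, whose TPM went the other way. There were 265 genes at an unadjusted p under 0.05, and without the 3 libraries against their sex label 6 genes passed: Kdm5d, Uty, Ddx3y, Eif2s3y, Fdx2 and Xist. Leaving out CON_female replicate 1 alone gave 5 genes, leaving out CON_female replicate 4, CON_male replicate 2 or HF_male replicate 3 gave 1, and leaving out any other single library gave 0; voom gave 0, with 676 unadjusted.

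Other genes of smallest p in the sex comparison did not pass. Tmem267 had a log2 difference of 0.51 ± 0.124 and the placental hormone gene Prl7b1 0.52 ± 0.15. Raver1, next to Fdx2 and nearly all within the gene model Gm38431, had 0.71 ± 0.207. Dpm1, a mannose synthase subunit gene, had 0.93 and Tnc 0.68. Inmt (-0.80), Ly6i (-0.87), the proline dehydrogenase gene Prodh (-0.46) and the keratin gene Krt80 (-0.44) were at lower values in libraries labelled male. Of 42 lists, 16 were called, 6 above and 10 below, and 1 with the estimated correlation, the Y-linked genes; all 9 genes of X inactivation and escape lay below 0 (mean -0.34, adjusted p = 2.12e-08; adjusted p = 0.47 with an estimated correlation). Yolk sac endoderm genes lay above 0 in 22 of 25 members, with a mean of 0.85 (adjusted p = 1.57e-11; adjusted p = 0.683 with an estimated correlation). Their mean was 0.35 without HF_male replicate 3 and 0.55 without CON_male replicate 4. The call ended after rescaling over protein-coding genes (0.90, adjusted p = 0.167), a total that holds 86600 TPM of Gm10800 in CON_female replicate 4. All 7 neutrophil genes lay below 0 (mean -0.29, adjusted p = 3.99e-05; adjusted p = 0.32 with an estimated correlation), among them S100a9 (-0.44). Decidua genes had a mean of -0.26 (adjusted p = 5.61e-12; adjusted p = 0.54 with an estimated correlation), with the homeobox genes Hoxa10 and Hoxa11 at -0.40, and natural killer cell genes lay below 0 in 8 of 8 members, with a mean of -0.34 (adjusted p = 4.57e-05; adjusted p = 0.683 with an estimated correlation). Without CON_female replicate 3 the neutrophil mean was -0.18 and the decidua mean -0.15. The natural killer cell call ended without CON_male replicate 3 (-0.25, adjusted p = 0.0592), and its mean was -0.19 without HF_female replicate 4 and -0.22 without HF_male replicate 4. Both this call (-0.037, adjusted p = 0.807) and that of the neutrophil genes (-0.032, adjusted p = 0.631) ended after median ratio scaling with the yolk sac and decidua covariates. The natural killer cell mean was -0.58 and that of the X inactivation and escape genes -0.51 without the 3 libraries against their sex label.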

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

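The tests on sex-linked RNA, on yolk sac RNA and on Fdx2 were chosen after the results were seen; the comparisons with other splits of the samples were chosen before. Of 256 groups of 4 placentas in which the highest or lowest library was compared with the other 3, 30 had a library that stood apart, where chance gives about 13. The measures included the genes named above and, added by hand, the Y-linked genes, Afp, Gm10800 and Gm10801. These added genes gave many of the 30, so the excess over 13 follows in part from the choice of measures.

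CON_female replicate 1 stood apart from the other CON_female placentas in Ddx3y (12.8 TPM, others at most 0.00637), Uty (5.45), Kdm5d (2.43) and Eif2s3y (5.48), and CON_male replicates 1 and 4 lacked these RNAs. An exchange of labels between the control groups needs a CON_female library with Y-linked RNA as partner: there is 1, which could pair with 1 of these CON_male libraries, and 0 are left for the other, so an exchange within these groups cannot account for all 3. Female cells mixed into a male sample are ruled out for the CON_male pair, whose highest Y-linked sum was 0.004% of the lowest in the other libraries labelled male. For CON_female replicate 1 such a mixture stays open, since its Y-linked sum lay -1.41 SD from the mean of the other libraries with Y-linked RNA. A single wrong label or a swap with a sample outside this set also stays open, and no biological explanation was tested.

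Yolk sac endoderm RNA stood apart in HF_male replicate 3, with a list mean of 7.78 (others 3.45 to 3.97) and 12000 TPM of Afp, and Afp also stood apart at 1440 TPM in CON_female replicate 1, 778 TPM in CON_male replicate 4 and 1380 TPM in HF_female replicate 2. Scaling of the libraries as the cause of the higher list in HF_male is argued against, as the mean log2 difference was 1.9 after median ratio scaling. Yolk sac tissue in the sample stays open: of 12 tested genes of a further list, written after this library was seen, 75% were at least 4-fold above their median over the other 15 libraries, under the bound of 80% set for it, against 1.08% of all tested genes outside the first list (84% of the 25 members of that list, by which the library was singled out, were no separate evidence). Paternal diet stays open, with an exact permutation p of 0.114 in libraries labelled male (two-sided, n = 4 per group, smallest possible 0.0286) while the difference of 0.003 in those labelled female (exact permutation p = 1) balances single libraries, at 0.77 without CON_female replicate 1 and -0.78 without HF_female replicate 2.

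Fdx2 was higher in libraries labelled male, at 7.84 ± 1.21 against 4.01 ± 2.45 TPM (SD, n = 8), while the gene model Gm38431, which spans Fdx2 and nearly all of Raver1 (chromosome 9, 21067514 to 21091997), had 2.6 ± 0.673 against 7.38 ± 3.75 TPM. Reads divided between overlapping gene models may account for it: the summed TPM of both differed by a log2 value of only -0.11, at 10.4 ± 0.92 against 11.4 ± 1.67 TPM. Fetal sex stays open. Of the 3 libraries against their sex label, 1 had an Fdx2 level on the side of its sex-linked RNA (8.5 TPM in CON_male replicate 1, 6.45 TPM in CON_male replicate 4 and 7.81 TPM in CON_female replicate 1, with the midpoint at 5.37). CON_female replicate 4, female by label and by sex-linked RNA, also lay above the midpoint, at 7.90 TPM. The other libraries labelled female without Y-linked RNA lay at 1.82 to 3.76 TPM, and all libraries with Y-linked RNA at 6.82 to 9.68 TPM.

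In CON_female replicate 3 the median ratio size factor was 1.36 (others 0.853 to 0.928), the mean of the hypoxia list 5.95 (others 5.45 to 5.53), Cyp2ab1 8.04 TPM (others at most 2.99) and Inmt 35.5 TPM (others at most 13.6). HF_male replicate 3 had a mean of 4.61 in the cholesterol synthesis list (others at most 3.67) and 4.18 TPM of Ppih (others at most 3.24). Hamp was at 0 TPM in CON_female replicate 2 (others at least 1.14). Tnc was at 1.94 TPM in CON_male replicate 3 (others at most 1.13) and 2.61 TPM in HF_female replicate 2 (others at most 0.754). In CON_male replicate 4 Mir382 was at 1.04 TPM and Mir669d at 0.714 TPM, and in CON_male replicate 2 Mir453 was at 1.85 TPM. Ly6i was at 3.42 TPM in HF_female replicate 4 (others at most 2.42). Uty and Eif2s3y stood at 0.0336 and 0.0539 TPM in HF_female replicate 3, where the others had at most 0.00472 and 0. Gm10800 was at 86600 TPM in CON_female replicate 4, 7600 TPM in CON_male replicate 4 and 164 TPM in HF_female replicate 4, and its neighbour Gm10801 at 8420, 825 and 22.4 TPM in the same libraries; others had at most 11.9 and 1.36 TPM.

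For the sire's diet and the interaction the count of genes that passed was 0, so every split gives as many by construction (35 of 35 in libraries labelled female, 35 of 35 in those labelled male, 100 of 100 for the average and 100 of 100 for the interaction), and the splits say nothing about chance there. The highest other split gave 1 gene in females, in males and for the interaction. For the average 1 other split gave 764 genes and 4 of the others gave any; such a split could follow a structure of the samples other than the labelled groups, which was not tested. For the sex comparison 2 of 100 splits gave 2 genes or more, the real one and another with 2. That share is small, but another split reached the same count and the real count fell to 0 under many other settings. Chance is therefore not firmly excluded there. For the gene lists chance cannot be excluded. In libraries labelled female 27 of 35 splits called as many as the real 8 lists, with up to 21, in those labelled male 32 of 35 called as many as the real 10, with up to 21, and in the average 92 of 100 called as many as the real 8, with up to 23.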

How the results depend on the processing

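The 6 settings that left out libraries against their sex label (without or with HF_male replicate 3), rescaled over protein-coding genes, used the yolk sac list as a covariate, joined median ratio scaling with 2 covariates, or left out the sex term were chosen after the results were seen, as were all settings for the lists of the interaction and sex comparisons and the decidua covariate for the natural killer cell list. Of the 37 settings, the fits to 1 sex alone covered that sex only and the one without the sex term the average only. In every diet comparison fitted (female, male, averaged) limma passed 0 genes, with 47 to 3295 genes at an unadjusted p under 0.05. The lowest number came from 9834 genes at a TPM minimum of 5. Sample weights gave 1477, 2838 and 3295 (female, male, averaged) of 14744 genes, where 737 would come up by chance. In the average, 799 without CON_female replicate 3 and 774 after protein-coding rescaling also lay above that number. With the replicate number as a block the diet counts were again 0, the sex count 1 (Gm8493), and the list calls 9, 10 and 9 (female, male, averaged); the block also ended the call of the stroma list in the interaction (adjusted p = 0.0514) and of the macrophage list in the sex comparison (adjusted p = 0.0572). The labels name nothing that placentas of a number share, and a pairing was not established: 10 of 24 same-number pairs correlated above 0.1, from -0.276 to 0.431, and 4 of 16 libraries correlated best with one of their own number. The interaction count was 1 (Gm49909) without the 3 libraries against their label, and also 1 without those and HF_male replicate 3; fewer libraries were fitted, and the cause was not tested. The sex count of 2 was 0 with a pseudocount of 0.25, no filter, FPKM, median ratio or quantile scaling, voom, sample weights, the decidua, junctional zone or yolk sac covariate, protein-coding rescaling, and median ratio scaling with covariates. It was 1 with a TPM minimum of 5 (Fdx2), 0 to 5 without single libraries, 6 without the 3 libraries and 8 without those and HF_male replicate 3. Y-linked genes entered the count without CON_female replicate 1 and without all 3 libraries, and did not without CON_male replicate 1 or 4 alone (count 0 in each); the cause of the other changes was not tested.

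Gene list calls fell to 0 in each diet comparison with the estimated correlation and with fry. Without single libraries they ranged from 6 to 13 in females, 9 to 14 in males and 6 to 14 in the average. Without the 3 libraries against their label they were 6 in females, 17 in males and 17 in the average, and without those and HF_male replicate 3 they were 7, 20 and 15; the cause was not tested. In the last setting the yolk sac list passed in the average also with an estimated correlation (mean 1.24, adjusted p = 0.035), where over the named settings that p was otherwise 0.131 or more; the setting also leaves out CON_female replicate 1 and CON_male replicate 4, the controls highest in Afp. Of 9817 recomputed values of 284 named genes and comparisons, 9697 kept their direction and side of the threshold. Another 27 no longer passed, 13 newly passed and 80, of genes that did not pass, changed sign. All 27 belonged to Fdx2 in the sex comparison, the only one of these results that had passed over all genes. The others had not passed, so keeping their side of the threshold was largely fixed in advance and says little about stability. For the lists called for diet 556 values were kept and 146 were no longer called. For the lists called in the interaction and sex comparisons, with the natural killer cell list under the decidua covariate, 599 kept the call and 173 lost it. The direction given by camera reversed in 0 of the calls kept, although the mean itself could change sign. Fetal endothelium did so in the interaction (-0.04, and 0.04 without CON_male replicate 3). Decidua genes did so in females (-0.10, and 0.11 without CON_female replicate 3, where the median over all tested genes was 0.153). In simulated data, a log2 change of 0.5 was recovered in 8.66% of genes in females and 11.3% in males, so changes of that size in 4 placentas per group are mostly not detectable here.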

Other observations

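Some imprinted genes of placental growth were abundant in the 16 placentas, and others were not. H19, a maternally expressed noncoding RNA, had 3100 ± 641 TPM (SD, n = 16) and its neighbour Igf2, the paternally expressed growth factor, 297 ± 56.7 TPM. The retrotransposon-derived Peg10 had 749 ± 144 TPM, the growth inhibitor Cdkn1c 324 ± 57.2 TPM and the receptor Igf2r 92.3 ± 17.5 TPM. Phlda2, which restrains placental growth, varied widely, at 11.2 ± 6.87 TPM and between 4.22 and 33.4 TPM. Mest had 60.6 ± 17.5 TPM, Dlk1 41.4 ± 14 TPM, Meg3 20.7 ± 10.1 TPM and Rtl1 6.38 ± 1.89 TPM.

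The microRNA genes of 2 placental clusters were looked at after the values were seen. Within Sfmbt2 (chromosome 2, 10370510 to 10595253), 44 genes with a microRNA name were tested, of which 35 lay above 0 in the averaged diet comparison, 27 in libraries labelled female and 39 in those labelled male. Their median log2 difference was 0.17, from -0.19 to 0.46, and 0 passed over these genes alone (limma, smallest adjusted p = 0.115). A further 41 microRNA gene models without such a name were tested there, of which 35 lay above 0, with a median of 0.14, from -0.16 to 0.52; over both sets together 0 passed (smallest adjusted p = 0.137). The host gene Sfmbt2 had 64.2 ± 12.7 TPM with control and 65.3 ± 5.58 TPM with high-fat sires (SD, n = 8). In the imprinted region from Meg3 to Mirg (chromosome 12, 109541001 to 109749460), 11 of 13 genes with a microRNA name lay above 0, with a median of 0.32. Of these, 0 passed over all genes and 3 over these genes alone (limma, smallest adjusted p = 0.0241), which is not independent evidence as the region was chosen on the same values. Meg3 had 16.2 ± 4 and 25.1 ± 12.4 TPM, Rian 50 ± 12 and 63.5 ± 24.3 TPM, and Mirg 6.49 ± 2.24 and 9.19 ± 4.33 TPM. These microRNA genes are shorter than a read and the copies within Sfmbt2 are alike, so their values are uncertain. The median log2 difference over all tested genes was itself 0.054 in the average, 0.021 in libraries labelled female and 0.084 in those labelled male. Counts above 0 alone therefore do not set the microRNA genes apart.

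The share of TPM held by the 7SL RNAs Rn7s1 and Rn7s2 went with the median ratio size factor of the other genes. Over 16 libraries the Pearson r with the log2 size factor was -0.849 (permutation p = 9e-05) and Spearman's rho -0.815 (permutation p = 2e-04), the only relation computed. Without CON_female replicate 3 and HF_male replicate 3, the libraries farthest from the median share, r was -0.695. Because TPM values sum to a fixed total, a relation of this sign follows in part from the unit itself. The group means of the share were 32.8% in CON_female, 36.5% in CON_male, 34.2% in HF_female and 35.7% in HF_male. After median ratio scaling, the first principal component across all tested genes held 26.8% of the variance. With its direction set so that Afp counted as positive, 16 of its 20 highest loadings were genes of the yolk sac list. HF_male replicate 3 scored 47.3 on it, and the next highest score was 20.5 in HF_female replicate 2. The component therefore follows HF_male replicate 3 in large part.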
